A study of Escherichia coli str. K-12 substr. MG1655 with 4 samples.

How the data were processed

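ChIP-seq libraries of σ70, of RNAP from rifampicin-treated cells and of RNAP from untreated cells were analysed, 1 library each. The design text speaks of duplicates, and whether a library pools them is not given in the sources used here. The mock IgG sample was not analysed here. Per the labels' protocols, cells were cross-linked with 1% formaldehyde for 30 min, chromatin was sonicated to 200 to 400 bp, and libraries were amplified by PCR. CASAVA 1.4 is named in the submitters' processing notes without a role. The aligner, the version of the sequence NC_000913 and the handling of repeated sequences and of duplicate reads are not given in the sources used here. Reads from near-identical copies such as ribosomal RNA operons are therefore uncertain.

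The deposited values are a score per base and strand, with the minus strand written as negative, and the feature names in the files mark the scores as subtracted. No depth normalization was seen in the values. The scores were tested for the form of a weight times a whole read count minus a second weight times a whole control count. At a tolerance of 0.006, 99.999% of the σ70 scores and 99.996% of the RNAP −Rif scores had that form. For σ70 the search allowed so many control counts that any score in even hundredths has the form. The σ70 share alone is thus weak support, and the form rests on the agreement between tracks given next. The read weights were 1, 0.995 and 0.939, and the control weights were 0.78, 0.00544 and 0.0607. The control counts recovered separately from σ70 and RNAP −Rif were equal at 99.995% of 476205 shared positions, and at 99.985% of the 123290 of these with a control count above 0. The RNAP +Rif control weight is below the tolerance, so a single control count cannot be seen in that library. The control was therefore checked, after the data were examined, at 7640 RNAP +Rif positions where the other tracks gave 5 or more control counts. There 99.9% of the scores lay within the tolerance with those counts, 46.6% with the counts shuffled among the positions and 0.0785% with the counts left out. The source of the control counts is not stated. One control was thus subtracted with very different weights, and σ70 positions whose reads were at or below 0.78 times the control count are missing from the file. Read counts recovered from the scores do not restore such positions. A second, smoothed σ70 score file, listing values of 0.5 or more by a rule not stated, was used only as an alternative.

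The planned analysis needed gene positions. The annotation at hand is on a stated version of the sequence and the files name none, so none of its coordinates were used and no genes were named. Promoter and gene body occupancy, the ratio of body to promoter, positions relative to gene starts and the gene lists were not computed. Following the fallback fixed before the data were examined, peaks are named by coordinates, the 6 highest per library and the 6 highest RNAP +Rif peaks with σ70 under 2. Long stretches, changes at σ70 peaks, flank ratios and correlations over peaks replaced the gene results and were chosen after the data were examined. The regions named for stretches were also chosen after their values were seen.

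The strand offset was estimated by cross-correlation, and strands were combined after moving each by 22 bp for σ70, 23 bp for RNAP +Rif and 29 bp for RNAP −Rif. The combined track was averaged over 201 bp and divided by the median of the library's 1 kb bins. That median held 173 recovered reads per kb for σ70, 383 for RNAP +Rif and 314 for RNAP −Rif. Maxima at 4 or more were peaks, and maxima under 300 bp apart were merged to the higher. Summits within 150 bp counted as shared, and 1000 random circular shifts gave the chance share. Stretches were runs of the averaged track at 4 or more over 1 kb or more. Windows around summits reached 100 bp to each side. A change was counted at 1 or more log2 units, with no test. Isolated σ70 sites for flanks had no second σ70 or RNAP +Rif site within 1500 bp and at least 4 times background at the summit in both RNAP libraries. A neighbouring RNAP −Rif peak did not remove a site. Shares carry exact Clopper-Pearson intervals, counts exact Poisson intervals and ratios the exact interval for 2 Poisson counts. Medians carry intervals from 1000 bootstrap draws and Spearman's rho from 200. All describe these libraries only.

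On simulated tracks with 1000 planted peaks, 990 peaks were called at the background of σ70 and 999 at that of RNAP +Rif, with 0 false peaks, and all 50 planted stretches were found. The planted peaks and stretches lay well apart, above the peak threshold, on a flat random background without pile-ups or a subtracted control. The simulation therefore checks the calling steps only and does not measure false peaks in the real tracks. Simulated scores of all 3 forms gave back 100% of the read counts. Control counts came back at 100% for the σ70 and RNAP −Rif forms and at 91.9% for the RNAP +Rif form, where they can only be estimated at positions listed in no other track. Alternatives were scaling by the genome mean or the lower quartile, thresholds of 3, 6 and 8, no strand shift, thinning to 3306561 reads, summit distances of 50 and 300 bp and the smoothed σ70 file. Added after the data were examined were recovered read counts, the σ70 control weight in all tracks, scores limited to 10 per position, other window sizes and other flank settings. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.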

Results

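Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 2 parts of the transcription machinery on the chromosome of Escherichia coli K-12 MG1655. Antibodies against σ70, the primary sigma factor that directs RNA polymerase (RNAP) to most promoters of growing cells, gave 1 library. Antibodies against the β subunit of RNAP gave 1 library from rifampicin-treated cells (+Rif) and 1 from untreated cells (−Rif). Rifampicin binds the β subunit and stops RNAP from extending very short transcripts, so that polymerase already past this stage can run off while polymerase at promoters cannot leave. Cells were grown in minimal medium with 0.2% glucose at 30 °C to an optical density of 0.6, and the treated cells received 150 µg/mL rifampicin for 30 min. The labels do not say whether the cells of the σ70 library were treated. A mock immunoprecipitation with IgG is the fourth sample of the series and was not analysed here. Each condition had 1 library, so no difference below has a replicate check and no p-value was computed.

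The scores summed to 2988725 for σ70, 5808379 for RNAP +Rif and 4547275 for RNAP −Rif. The read counts recovered from them were 3306561, 5845997 and 4871650. Both strands held nearly equal numbers of recovered reads, for example 1653821 and 1652740 for σ70. The 2 strands were offset by 45 bp for σ70, 46 bp for RNAP +Rif and 59 bp for RNAP −Rif. Intervals given below are 95% intervals. Those of reads and of ratios describe counting error only, and reads copied by PCR are not independent molecules. Those of shares of peaks, medians and rho describe variation over peaks, sites, stretches or windows within these libraries, not between replicates. Positions holding 20 or more reads took 39.8%, 41.0% and 30.0% of the recovered reads of σ70, RNAP +Rif and RNAP −Rif. Enrichment below is the mean score over 201 bp, or over a named region, divided by the library's median 1 kb bin. Regions are given by position on the sequence named NC_000913, whose version the sources used here do not give, and without gene annotation.

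The first question was how far each protein was concentrated at discrete sites. All 3 libraries showed narrow peaks over a low background, and σ70 was the most concentrated. The 1% of 200 bp bins with the highest scores held 45.6% of the σ70 score, against 28.6% for RNAP +Rif and 29.2% for RNAP −Rif. With scores limited to 10 per position the shares were 23.0%, 13.1% and 14.7%. At 4 or more times background, 2111 peaks were found for σ70, 2200 for RNAP +Rif and 2380 for RNAP −Rif. The highest σ70 peak stood at 1407 times background, the highest RNAP −Rif peak at 535 and the highest RNAP +Rif peak at 273. Median widths at 0.5 times the summit height were 226 bp for σ70, 216 bp for RNAP +Rif and 272 bp for RNAP −Rif. Widths were measured on the track averaged over 201 bp, so values near 201 bp mostly reflect that window and not the extent of binding. The upper quartile of the widths was 576 bp for RNAP −Rif, against 246 bp for RNAP +Rif. With scaling by the genome mean in place of the median bin the peak counts were 729, 1036 and 905, so the numbers of peaks depend on the scaling.

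The highest σ70 peak had its summit at position 4047929, with enrichment of 1407 for σ70, 159 for RNAP +Rif and 403 for RNAP −Rif. It rested on 39876 σ70 reads within 100 bp of the summit (interval 39486 to 40269). The next σ70 summits lay at 4176367, 1640444, 3717925, 1049940 and 4603746, with enrichment between 857 and 1128. All 6 had an RNAP peak within 32 bp in the +Rif library and within 44 bp in the −Rif library. RNAP +Rif enrichment was below RNAP −Rif enrichment at each of the 6, with +Rif over −Rif ratios from 0.202 at 1640444 (interval 0.194 to 0.210) to 0.656 at 1049940 (interval 0.644 to 0.668). The peak at 1640444 ranked number 3 for σ70 and number 383 for RNAP +Rif.

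The highest RNAP −Rif peak lay at 3948309, with enrichment of 535 against 94.3 in RNAP +Rif, a +Rif over −Rif ratio of 0.176 (interval 0.172 to 0.181). The remaining 5 of the 6 highest −Rif peaks lay at 3694772, 2922537, 4047950, 1049947 and 3465021. Their +Rif over −Rif ratios ran from 0.258 at 3465021 to 0.645 at 1049947. All 6 had a σ70 peak within 21 bp. These peaks were chosen for being high in −Rif, which by itself lowers such ratios.

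The highest RNAP +Rif peak lay at 1565322, where enrichment was 273 in +Rif, 53.2 in −Rif and 29.5 for σ70. The +Rif over −Rif ratio there was 5.13 (interval 4.94 to 5.32). Peaks at 3851240 and 480051 were also higher with rifampicin, with ratios of 5.43 (interval 5.22 to 5.65) and 3.40 (interval 3.29 to 3.51). At 4049042 the ratio was 1.30, and at 1049908 and 2922556 it was 0.716 and 0.519. These 6 peaks each had a σ70 peak within 129 bp, which ranked between number 5 and number 497 among the σ70 peaks. They were chosen for being high in +Rif, which by itself raises such ratios.

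**Figure D1:**
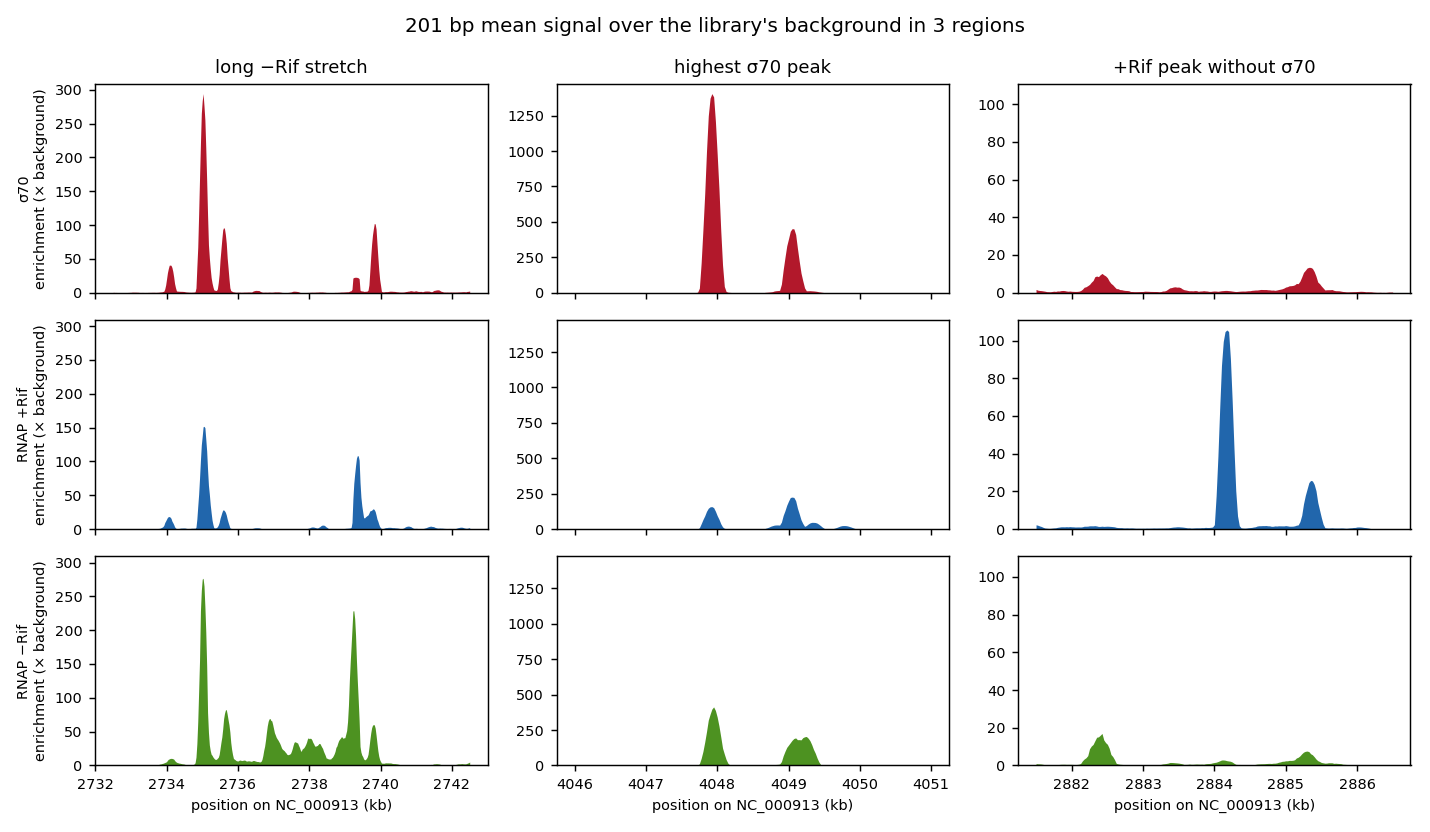
Enrichment (201 bp mean score over the library's median 1 kb bin) against position on NC_000913 in kb, for σ70 (top), RNAP +Rif (middle) and RNAP −Rif (bottom), with 1 vertical scale per column. The left column holds the longest RNAP −Rif stretch (2734801 to 2740016), filled between its peaks only in −Rif, the middle column the highest σ70 peak (1407 times background), and the right column a +Rif peak at 2884170 with enrichment of 106 in +Rif and 2.59 in −Rif.

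The second question was how many RNAP sites coincided with σ70. Most RNAP peaks of both libraries lay at σ70 peaks, and the share was higher in the −Rif library. The σ70 cells may share the state of either library, so this difference is not read as an effect of rifampicin. Of the 2200 RNAP +Rif peaks, 1390 (63.2%, exact binomial interval 61.1 to 65.2) had a σ70 summit within 150 bp. Of the 2380 RNAP −Rif peaks, 1685 (70.8%, interval 68.9 to 72.6) had one. Random circular shifts of the σ70 peaks gave a mean of 13.7% for both, and the highest of 1000 shifts gave 16.0% for +Rif and 15.8% for −Rif. Among the 200 highest peaks the shares rose to 83.0% (166 peaks, interval 77.1 to 87.9) for +Rif and 96.5% (193 peaks, interval 92.9 to 98.6) for −Rif. Seen from σ70, 65.8% of its 2111 peaks had a +Rif peak and 79.8% a −Rif peak. Both RNAP libraries had a peak at 1223 of the σ70 peaks and neither had one at 259. Of the 200 highest σ70 peaks, 197 had a +Rif peak and 199 a −Rif peak. Summits of paired peaks lay a median of 19 bp apart for σ70 and +Rif, 21 bp for σ70 and −Rif and 33 bp for the 2 RNAP libraries.

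Most RNAP +Rif peaks without a σ70 peak had no called RNAP −Rif peak either. Of these 810 peaks, 214 (26.4%) had an RNAP −Rif peak, against 1213 of the 1390 (87.3%) with a σ70 peak. The 2 sets were not matched on height. Among the 200 highest +Rif peaks, 28 of the 34 without a σ70 peak had a −Rif peak, so the low share does not hold for strong peaks. The σ70 track carried a much heavier subtraction of control counts than the RNAP tracks. The share of +Rif peaks with a σ70 peak was 63.3% with the same control weight in all tracks and 63.6% in recovered read counts, which do not restore fully subtracted positions. With summits allowed only 50 bp apart it was 48.7%, and with 300 bp 70.1%.

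Among +Rif peaks, 465 of 2200 (21.1%) had σ70 enrichment under 2. The 6 highest of them lay at 738192, 2884170, 2798124, 3489663, 1956772 and 2663415, with +Rif enrichment between 77.3 and 110. At 2884170 enrichment was 106 in +Rif, 2.59 in −Rif and 1.24 for σ70, from 8115, 165 and 42 reads, and the +Rif over −Rif ratio was 40.8 (interval 35.0 to 47.9). At 3489663 this ratio was 30.6 (interval 26.3 to 35.7) and at 738192 it was 21.8 (interval 19.5 to 24.4). The lowest ratio of the 6 was 7.55, at 2798124. Choosing these peaks for being high in +Rif by itself raises such ratios. The nearest σ70 peaks lay between 548 bp (2798124) and 2012 bp (2663415) away.

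The third comparison asked how RNAP occupancy at σ70 sites differed with rifampicin. Changes went both ways, and over all σ70 peaks RNAP was lower in +Rif at more sites than higher. The σ70 peaks that define the sites come from cells whose treatment is not given. Over the 2111 σ70 peaks, median RNAP enrichment within 100 bp of the summit was 7.13 in +Rif and 9.45 in −Rif. The median log2 ratio of +Rif to −Rif was −0.31 (bootstrap interval over peaks −0.40 to −0.23), with an interquartile range from −1.45 to 0.85. RNAP was higher in +Rif by at least 1 log2 unit at 483 peaks, lower by at least as much at 714 and within these bounds at 914. Among the 528 peaks with the highest σ70, 102 were higher, 150 lower and 276 within the bounds, with a median of −0.21. Among the 528 peaks with σ70 enrichment from 10.9 to 28.3, 157 were higher and 166 lower, with a median of −0.11 and an interval from −0.26 to 0.11 that spans 0. Among the 527 peaks with σ70 enrichment from 6.23 to 10.9, 109 were higher and 209 lower, with a median of −0.62. Among the 528 weakest σ70 peaks, 115 were higher and 189 lower, with a median of −0.39. Scaling by the lower quartile of 1 kb bins moved every ratio by −0.30 log2 units and gave 380 higher and 855 lower. The labels name no spike-in, so each value is relative to its own library's background and not an absolute amount.

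The fourth comparison concerned RNAP spread along the chromosome away from its peaks. Long enriched stretches were a feature of the RNAP −Rif library. At 4 or more times background over 1 kb or more, 100 stretches were found in −Rif, 10 in +Rif and 26 for σ70. They covered 162 kb and held 26.2% of the score in −Rif, against 11.7 kb and 2.54% in +Rif and 34.7 kb and 4.76% for σ70. The longest reached 5216 bp in −Rif, 1291 bp in +Rif and 2921 bp for σ70. Stretches of 2 kb or more numbered 19 in −Rif, 0 in +Rif and 1 for σ70.

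The longest −Rif stretch ran from 2734801 to 2740016, with mean enrichment of 45.0 in −Rif, 15.4 in +Rif and 22.5 for σ70. Its +Rif over −Rif ratio was 0.342 (interval 0.338 to 0.347), and 33.6% of it reached 4 times background in +Rif and 28.2% for σ70. The stretch from 2102751 to 2107826 had a ratio of 0.438, that from 3794810 to 3799487 a ratio of 0.523 and that from 3438659 to 3442202 a ratio of 0.545. In the stretch from 2724858 to 2728315, mean enrichment was 11.6 in −Rif and 2.89 in +Rif, a −Rif over +Rif ratio of 4.00 (interval 3.86 to 4.15). Its highest +Rif window, at 22.9, was nearly matched in other long −Rif stretches. The values were 22.9 from 224921 to 226721, 22.9 from 3940741 to 3942653 and 22.6 from 3423904 to 3425903. They were 22.4 from 4034450 to 4036469, 22.3 from 4207049 to 4209207 and 22.1 from 4165561 to 4167566. Beside them lay stretches starting at 226781, 3422449, 3942750, 4036473, 4167991 and 4209286. In these the highest +Rif windows stood between 11.7 and 12.8, and 0% of each reached 4 times background for σ70. Such stretches may be near-identical copies of a repeated sequence, which was not tested. Copies would not be separate regions in the counts of stretches above and below, and the intervals do not cover uncertain placing of their reads. Of the 100 stretches, 55 were lower in +Rif by at least 1 log2 unit, 42 lay within 1 unit and 3 were higher by at least as much. The median log2 ratio was −1.17, with an interquartile range from −1.85 to −0.45. These stretches were chosen for being high in −Rif, which by itself lowers such ratios. A +Rif window of 201 bp at 4 or more times background lay in 98 of them, and a σ70 window in 94. The median part of a stretch at 4 or more times background was 60.7% for σ70 and 38.6% in +Rif, and median σ70 enrichment over the stretches was 15.9.

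**Figure D2:**
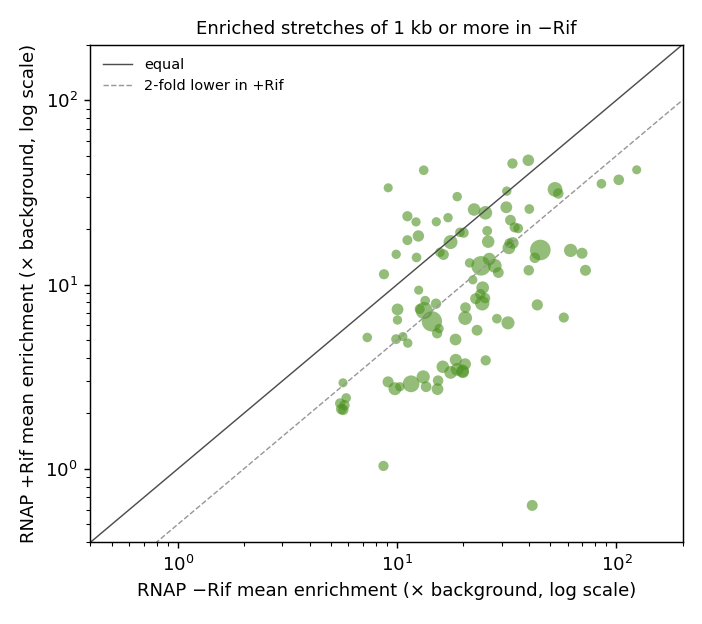
Mean RNAP enrichment in +Rif (vertical, log scale) against −Rif (horizontal, log scale) for the 100 stretches at 4 or more times background over 1 kb or more in −Rif. Each point is 1 stretch with its area proportional to length; the solid line marks equal enrichment and the dashed line a 2-fold lower value in +Rif, reached by 55 stretches.

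Of the 10 long stretches in RNAP +Rif, 3 were higher than in −Rif by at least 1 log2 unit, 2 were lower by at least as much and 5 lay within these bounds. These stretches were chosen for being high in +Rif, which by itself raises such ratios. That from 3364784 to 3365960 had mean enrichment of 52.1 in +Rif, 8.19 in −Rif and 5.08 for σ70, a +Rif over −Rif ratio of 6.36 (interval 6.12 to 6.61). That from 1553621 to 1554789 had enrichment of 67.4 in +Rif and 16.4 in −Rif, a ratio of 4.12 (interval 4.00 to 4.23). That from 3763946 to 3765230 had a ratio of 2.11 (interval 2.04 to 2.19). The stretch from 581895 to 583072 was lower in +Rif, at 9.59 against 38.2, a ratio of 0.251 (interval 0.243 to 0.260). The stretch from 1639564 to 1640615 was also lower in +Rif, at 30.4 against 89.0, and had σ70 enrichment of 275. Scaling by the genome mean left 11 stretches in −Rif and 0 in either other library, and scaling by the lower quartile gave 264, 35 and 106.

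Around isolated σ70 sites the RNAP signal fell below background within 1 kb of the summit in both conditions. At 149 sites with no second σ70 or RNAP +Rif site within 1500 bp, median summit enrichment was 24.6 for σ70, 22.1 for RNAP +Rif and 12.3 for RNAP −Rif. Between 300 and 1000 bp from the summit the median was 0.607, 0.562 and 0.726 times background. The median flank to summit ratio was 0.0292 in +Rif (interval 0.0221 to 0.0355) and 0.0515 in −Rif (interval 0.0405 to 0.0647), and the ratio was lower in +Rif at 102 of the 149 sites. A neighbouring −Rif peak did not remove a site, which favours lower flanks in +Rif. Flanks lay below the background of the whole library in all 3 libraries, so the median ratios turned negative when a background of 1 was subtracted and do not measure polymerase in the flanks.

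The fifth comparison set peak strength of σ70 against RNAP. RNAP peak strength followed σ70 more closely in the −Rif library than in the +Rif library. Whether the cells of the σ70 library were treated is not given, so this difference is not read as an effect of rifampicin. Over 3437 windows of 201 bp at the pooled peaks, Spearman's rho between σ70 and RNAP −Rif was 0.63 (interval 0.61 to 0.65) and Pearson's r of log2 enrichment was 0.70. Between σ70 and RNAP +Rif the values were 0.37 (interval 0.34 to 0.40) and 0.44, and between the RNAP libraries 0.24 (interval 0.21 to 0.27) and 0.29. These 3 correlations are across windows of single libraries, which are not independent replicates. The windows were chosen as peaks of at least 1 library. That choice leaves out windows low in every library, which by itself can lower rho. At windows of peaks at 8 or more times background the rho of the 2 RNAP libraries was 0.13.

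**Figure D3:**
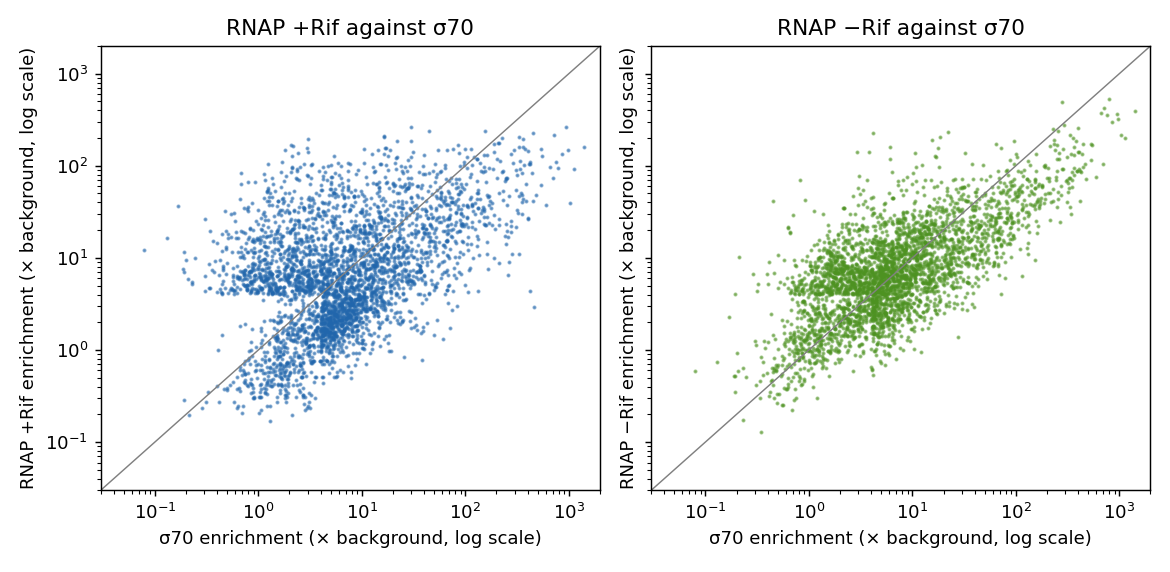
RNAP enrichment in +Rif (left, vertical, log scale) and −Rif (right) against σ70 enrichment (horizontal, log scale) at 3437 windows of 201 bp around the pooled peaks. Each point is 1 window and the line marks equal enrichment; the left cloud is wider (rho 0.37) than the right one (rho 0.63), with many windows low in σ70 and high in +Rif.

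The part of the chromosome away from σ70 peaks held a larger share of the +Rif reads than of the −Rif reads. Positions more than 500 bp from any σ70 peak made up 63.9% of the chromosome. They held 21.6% of the recovered +Rif reads, 16.6% of the −Rif reads and 10.5% of the σ70 reads. These shares include background reads, which were not separated from RNAP signal, and depend on how much of each library lies elsewhere. There were 513 RNAP +Rif peaks there and 367 RNAP −Rif peaks. Signal at 4 or more times background covered 111 kb of this part in +Rif and 91.1 kb in −Rif. By construction the σ70 library had no peak in this part. As the treatment of its cells is not given, these differences are not read as effects of rifampicin.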

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

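The control-subtraction tests on +Rif peaks and the hypothesis of another sigma factor were written after the results were seen, and the form of the first test was changed after its first outcome; the remaining tests of this part were written before their results.

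A signal appeared in the control counts that the report's comparisons do not use. Within 100 bp of σ70 summits there were 0.645 control counts per listed position (interval 0.643 to 0.648), against 0.178 (interval 0.177 to 0.180) more than 500 bp from every peak, a ratio of 3.62. Positions enter the files only where a library has reads, which could raise the control at peaks. Among positions with exactly 1 RNAP −Rif read the ratio was 4.71, which argues against this as the whole cause. What the control is, and whether it is the mock IgG sample, is not stated, and no biological explanation was tested.

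Of the 200 highest RNAP +Rif peaks, 34 had no σ70 peak within 150 bp, with median enrichment of 97.4 in +Rif, 11.4 in −Rif and 2.38 for σ70; for 14 of them a σ70 peak lay within 300 bp. Heavier control subtraction in the σ70 track may account for missing calls, since 5 of the 34 reached 4 times background in recovered counts, the first test, but 28 did when an estimate of the reads that subtraction could have removed at positions listed in an RNAP track (median 91.5 per window) was added, with the background left unraised. Too few σ70 reads stays open as well, and so does subtraction as the cause of the low level: the σ70 count reached that expected from the 166 shared peaks (median 1527) at 0 of 34 peaks, both without and with the removed reads. These peaks were chosen for lacking a σ70 peak, which holds most of their windows under 139 reads while the lowest expected count was 1144, so the selection fixed this outcome and these counts decide nothing. RNAP held by another sigma factor stays open as a hypothesis: 28 of the 34 also had a −Rif peak, and start sites of other sigma factors were not used here.

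The long RNAP −Rif stretches outnumbered those of +Rif by 100 to 10, with possible copies of repeated sequences counted separately. Pile-ups at single positions are argued against, since the ratio was 9.9 with scores limited to 10 per position. Different control weights and different depth are argued against in the same way, with ratios of 11.1 at the same control weight and 10.8 after thinning to the same number of reads. That polymerase moving along transcribed regions made the stretches and was lost under rifampicin is a hypothesis that was not tested, and σ70 reached 4 times background over a median of 60.7% of each stretch, more than the 38.6% of +Rif. Other differences between these 2 libraries, 1 per condition, cannot be separated from the treatment.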

How the results depend on the processing

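Recovered read counts, the σ70 control weight in all tracks, scores limited to 10 per position, and all settings for stretches, changes, flanks and window sizes were chosen after the data were examined. Of 158 alternative values, 88 stayed within the interval or within 1.5 times the main count, 67 moved further and 3 changed sign. Planned gene-based alternatives were not run, because no gene positions were used. No paired analysis was possible because each condition had 1 library. The cause was not tested for any value below, except that thresholds and distances by construction admit fewer or more peaks.

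Scaling by the genome mean gave 729 σ70, 1036 RNAP +Rif and 905 RNAP −Rif peaks, and 0, 0 and 11 stretches of 1 kb or more. Scaling by the lower quartile gave 3364, 3375 and 4237 peaks and 106, 35 and 264 stretches, with a median log2 change at σ70 peaks of −0.60 in place of −0.31. Threshold 8 gave 1327, 1428 and 1449 peaks and 3, 0 and 24 stretches. Threshold 6 gave 6, 3 and 57 stretches, and threshold 3 gave 43 for σ70. A minimum length of 2 kb left 1, 0 and 19. With scores limited to 10 per position, the highest 1% of 200 bp bins held 23.0%, 13.1% and 14.7% of the score. RNAP −Rif had more stretches than RNAP +Rif under every setting run.

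The share of RNAP +Rif peaks with a σ70 peak was 48.7% at 50 bp, 70.1% at 300 bp, 67.7%, 59.1% and 57.6% at thresholds 3, 6 and 8, and 59.5% with the smoothed σ70 file. For RNAP −Rif it was 54.4% at 50 bp, 77.1% at 300 bp, 67.5% and 66.6% at thresholds 6 and 8, and 65.8% with the smoothed file. The −Rif share was the higher one under every setting run.

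Median flank to summit ratios for RNAP +Rif and −Rif were 0.0104 and 0.0237 with the genome mean, 0.0478 and 0.0659 with the lower quartile, 0.0473 and 0.0655 at floor 2, 0.0141 and 0.0315 at floor 8, and 0.118 and 0.152 at all σ70 peaks. With a background of 1 subtracted they changed sign, to −0.0165 and −0.0164, as did σ70 at −0.0128. As both RNAP values nearly coincided there, no difference in flanks rests on these ratios.

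Spearman's rho with half-windows of 200 bp was 0.43 for σ70 and +Rif, 0.67 for σ70 and −Rif and 0.30 for the RNAP libraries. At peaks of 8 or more it was 0.26, 0.57 and 0.13. At windows of 2 or more in either library it was 0.28 for σ70 and +Rif and 0.54 for σ70 and −Rif. The order of the 3 values was kept in each case. Thinning to 3306561 reads left 2200 RNAP +Rif and 2401 RNAP −Rif peaks, so no limit from depth was seen in these counts.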

Other observations

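The tests and regions of this part were chosen after the data were examined, except that the prediction on the place of the +Rif maximum was written before its result.

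The RNAP −Rif stretch with the lowest +Rif over −Rif ratio ran from 1319834 to 1321308. Mean enrichment there was 41.3 in −Rif, 0.633 in +Rif and 1.13 for σ70, from 19082, 358 and 299 reads. The ratio was 0.0153 (interval 0.0138 to 0.0170), and no part of the stretch reached 4 times background in +Rif. Whether these −Rif reads came from the chromosome of the cultured cells or from other DNA in that library was not tested, so the ratio is not read as an effect of rifampicin. The stretch from 2039107 to 2040595 also had little σ70, at 3.26, with enrichment of 72.2 in −Rif and 11.9 in +Rif. In the stretch from 83088 to 84351, σ70 stood at 76.9 and −Rif at 57.5, against 6.62 in +Rif. On the other side, the stretch from 3165756 to 3166770 was higher in +Rif, at 33.5 against 9.11, a ratio of 3.67 (interval 3.53 to 3.83), and that from 2707245 to 2708391 had a ratio of 3.15 (interval 3.05 to 3.25).

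The hypothesis that the long −Rif stretches run from a start site at one end was tested by the place of the +Rif maximum. In 98 stretches its median distance from the nearer end was 0.215 of the stretch length (bootstrap interval 0.180 to 0.242), against 0.25 for a random place. Of 10000 sets of random places, 780 had a median as low. The whole interval lay above 0.15, the value the median had to stay under for the hypothesis. The interval also spanned 0.2, the bound set against the hypothesis. Stretch ends were taken from a track averaged over 201 bp, which keeps the summit of a peak at an end inside the stretch. In the shorter stretches this alone raises the distance. Neither the bounds nor the 0.25 of a random place allow for it, so the test cannot decide for or against the hypothesis.

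A smooth gradient along the chromosome was fitted to 10 kb medians with a free phase. The fitted highest over lowest point was 1.14 for σ70, 1.18 for RNAP +Rif and 1.06 for RNAP −Rif. Shuffled bins gave 95th percentiles of 1.22, 1.23 and 1.34, all above the fitted values. With the lower quartile of 1 kb bins RNAP +Rif reached 1.19 against 1.17 in shuffled bins, but with bins under 2 times background it was at 1.12 against 1.13.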
